A study of Mus musculus with 98 samples.

How the data were processed

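DNA of 54 primary tumours and 44 lung metastases was labelled with Cy5 and spleen DNA of wild-type BALB/c mice with Cy3, per the labels, and the dyes were not swapped. The 98 arrays lay on 26 slides in 5 scan batches, and 28 metastases lay on the slide of their own primary tumour. Per the file headers, the deposited intensity values were made with Feature Extraction 10.7.3.1, which subtracted background and scaled the dyes linearly, for an array design on build mm9. The submitters' processing notes name build mm10, whose use is not given in the sources used here. A table of log2 values deposited by the authors covers 170297 of 170305 probes. Its column medians lay between -0.00545 and 0.00497, and its correlation with the log2 ratios computed here had a median of 0.867 (0.670 to 0.973). Its centring and direction therefore match a tumour over reference log2 ratio, and the further correction applied to it is not given in the sources used here.

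The log2 ratio of processed red over green signal was computed after leaving out 6575 control spots and spots marked as non-uniform. Spots of one probe were averaged, and each array was centred on its autosomal median. Between 372 and 1679 spots per array were not well above background. Segments were found per chromosome by penalised least squares with a penalty of 4 and at least 5 probes, and called at a mean of at least 0.2 or at most -0.2. The derivative log ratio spread, a measure of probe noise, ranged from 0.106 to 0.498 and exceeded 0.3 in 12 arrays, 10 of them primary tumours. A chromosome counted as gained or lost when at least 50% of its probes lay in calls of that direction. No pair of arrays held identical values.

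Samples were paired by the mouse number in the titles, and metastases of one mouse were averaged, so that the mouse was the replicate. Shares, counts and similarities were tested by two-sided permutation with 100000 resamples or exactly where few mice allowed it. Bins of 1 Mb with at least 10 probes and autosomes were tested with limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment. Other steps used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Regions and genes were chosen by a rule set before the data were examined. It took the most frequent chromosome-wide events and focal calls in at least 3 mice, up to 10 by number of mice. It also took listed genes altered in at least 10% of primary tumours or mice with metastases. Focal calls are named down to 19 mice, with ties, and those in fewer mice were picked after seeing the data. Only part of the genes that passed is named.

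Several planned analyses need a gene annotation of build mm9, which was not used here. The gene table used, of assembly GRCm38.p6, gave only the chromosome of each of the 142 listed genes. Tests of single genes, of antigen receptor loci and of Erbb2 exon probes and the GC correction were therefore not run, and antigen receptor loci were not left out of the called length as planned. The upper limit of similarity set by the altered shares, the depth of the chromosome 4 interval, the events by number of metastases and the share of all genes on the named chromosomes were computed after seeing the data. The normexp alternative (offset 50) used median signals in place of the planned mean signals.

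Arrays were simulated at the real autosomal probe positions with noise independent between probes. Noise that runs along a chromosome was not simulated, so recovery and false calls in the real arrays can differ. In the simulation, all 19 events of 1000 probes with a log2 shift of 0.35 were recovered at noise up to 0.45. Of events of 100 probes, 19 were recovered at a noise of 0.3 and 0 at 0.45, and of events of 20 probes 1 at 0.2. For the paired bin comparison, shifts were put into 200 of 2383 bins of sign-flipped pairs, each of the same size in all 28 mice. There limma recovered 66% of bins shifted by 0.1 and 96% of those shifted by 0.2, with 32 false calls among the other bins. Shifts in only part of the mice, or in only a few bins, were not simulated. The recovery given does not apply to those. With no effect simulated, the sign-flip test gave p under 0.05 in 5.4% and the permutation test in 6.4% of 500 simulations. Alternatives covered the calling threshold, penalty, background correction, the authors' table, dim probes, centring, probe medians, pairing, choice of metastases, slide, scan batch, noisy arrays, bin width, segment length and each mouse left out.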

Results

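Copy number was measured by array comparative genomic hybridisation, in which tumour DNA and reference DNA compete for the same probes, in 98 samples from 54 mice. The tumours arose from 2 mm mammary gland fragments of BALB-NeuT mice, which carry an activated rat Erbb2 (neu) transgene, transplanted to BALB/c recipients without the transgene, whose own mammary epithelium had been removed. Primary tumours were removed at 5 to 10 mm, and metastases were collected 17 weeks after surgery. There were 54 primary tumours, 1 per mouse, and 44 lung metastases from 28 of these mice. Of the 28 mice, 18 had 1 metastasis array, 4 had 2 and 6 had 3. The labels do not say whether the other 26 mice were free of metastases. Each array held 174305 non-control spots for 170305 probes. The number of arrays limits the precision of every comparison below.

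Loss of chromosome 4 was the most frequent alteration. At least 50% of its probes were lost in 45 of 54 primary tumours (83.3%, Wilson 95% interval 71.3 to 91.0%) and in 36 of 44 metastases (81.8%, 68.0 to 90.5%). The mean log2 ratio of chromosome 4 in the arrays with this loss was -0.56 ± 0.15 (SD). In primary tumours it was followed by gain of chromosome 12 in 8, loss of chromosome 13 in 7, and loss of chromosome 7 and gain of chromosome 15 in 6 each. Chromosome 1 was lost in 5 primary tumours (9.26%) and in 0 of 44 metastases, for which the Wilson interval reaches 8.03%. In metastases the next most frequent events were loss of chromosome 13 in 13, gain of chromosome 2 and loss of chromosome 14 in 12 each, and gain of chromosome 12 in 8. Several metastases of one mouse are not independent, so the Wilson intervals over 44 metastases are too narrow. For a count of 0 of 28, the number of mice with metastases, the Wilson interval reaches 12.1%. Loss of chromosome 13 in 13 metastases came from 5 mice, gain of chromosome 2 from 8 mice and loss of chromosome 14 from 7 mice.

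**Figure D1:**
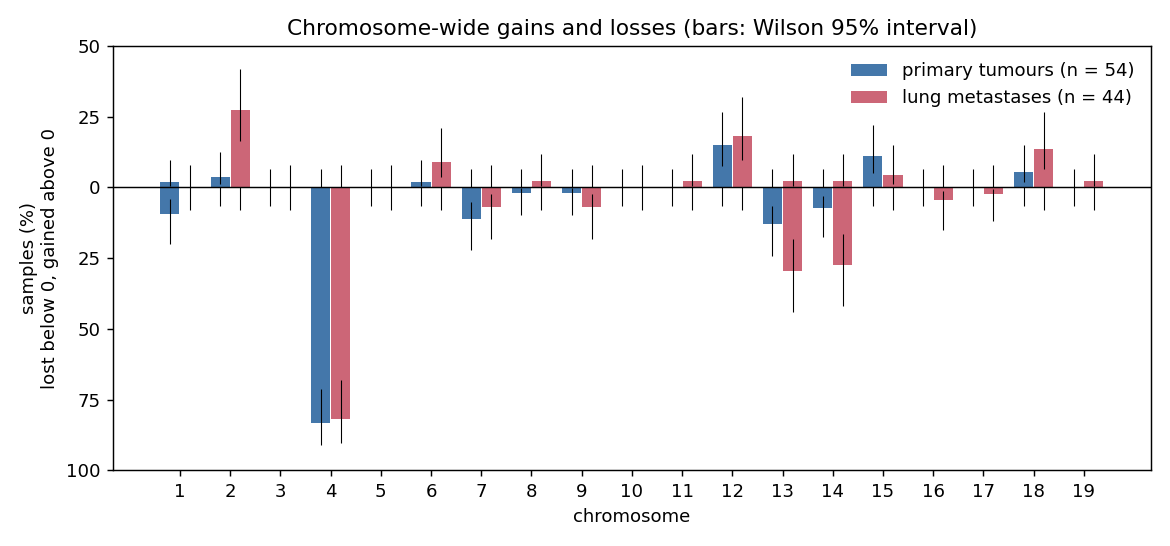
Percentage of the 54 primary tumours and 44 lung metastases with a chromosome-wide gain (above 0) or loss (below 0) of each autosome, with Wilson 95% intervals. The intervals treat metastases of one mouse as independent and are too narrow for metastases. Chromosome 4 was lost in 83.3% of primary tumours and 81.8% of metastases, and chromosome 2 was gained in 3.70% and 27.3%.

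The listed genes could be tied only to their chromosome, so the frequencies given for a gene are those of its chromosome and not of the gene itself. Of 142 listed genes, 64 lay on a chromosome gained or lost in at least 10% of primary tumours or of mice with metastases, or 45.1%. These were 9 of 19 autosomes and held 45.6% of 21887 protein-coding genes. Chromosomes 2, 12, 15 and 18 met the bound by gain and chromosomes 4, 7, 9, 13 and 14 by loss. Among the 24 tumour suppressors, 10 did so. Cdkn2a and Cdkn2b, which encode inhibitors of cell cycle kinases, and Arid1a, a chromatin remodelling subunit, lie on chromosome 4. Rb1 and Bap1 lie on chromosome 14, lost in 7.41% of primary tumours and in metastases of 25% of mice. Map3k1 lies on chromosome 13, and Apc and Smad4 lie on chromosome 18, which was gained. Among 18 cell cycle and MYC genes, 12 lay on such chromosomes, including Myc and Skp2 on chromosome 15, Mycn on chromosome 12, Mycl on chromosome 4, and Aurka, E2f1 and Bmi1 on chromosome 2. Among 16 genes of epithelial-mesenchymal transition and invasion, 10 did so, with Snai1, Zeb2, Vim and Mmp9 on chromosome 2. Among 16 hormone, WNT and RANK genes, 10 did so, including Elf5, Notch1 and Gata3 on chromosome 2 and Wnt4 on chromosome 4. Among 24 receptor tyrosine kinase and RAS pathway genes, 7 did so, including Src on chromosome 2, Akt1 on chromosome 12 and Igf1r on chromosome 7. Among 16 DNA repair genes, 8 did so, including Atm, Atr and Chek1 on chromosome 9. Among 15 metastasis suppressors, 4 did so, with Cd82, Gsn and Cd44 on chromosome 2, and among 16 antigen presentation and interferon genes, 4 did so, with Jak1, Ifnb1 and Ifna4 on chromosome 4. Erbb2 itself lies on chromosome 11, which was gained across most probes in 0 of 54 primary tumours and 1 of 44 metastases.

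The matched samples address whether metastases carry more alterations than the primary tumour of the same mouse. The altered share of the autosomes was 13.4% ± 9.79 (SD, n = 28) in matched primary tumours and 15.8% ± 11.5 (SD, n = 28) in the mouse means of metastases. The paired difference was 2.43 percentage points (95% bootstrap interval -1.37 to 6.37), higher in metastases of 16 of 28 mice, with a two-sided sign-flip permutation p of 0.245. Subtracting each probe's median over all arrays, gave 4.79 points with a permutation p of 0.0386. That step takes away most calls of the common chromosome 4 loss, but not evenly. The loss was still called in 2 primary tumours and 9 metastases. Chromosome 4 was called gained in 12 primary tumours and 9 metastases, among them the 9 and 8 without the loss before the step. These calls enter the 4.79 points. Without chromosome 4, an alternative chosen after seeing the data, the same step gave 3.66 points (permutation p = 0.117). Log2 ratios as measured gave 2.92 without chromosome 4 (permutation p = 0.158). Leaving out noisy arrays gave 0.953 points (permutation p = 0.639), 0.968 came from the authors' table (permutation p = 0.580), a calling threshold of 0.1 gave 4.92 (permutation p = 0.139), and leaving out mouse 3635 gave 1.5 (permutation p = 0.429). The number of called segments was 13.8 higher in metastases (interval -3.95 to 33.5, permutation p = 0.181), and over the alternatives it ranged from 3.1 to 39.0 with no permutation p under 0.05. With single mice left out it ranged from 7.78 without mouse 3700 (permutation p = 0.357) to 18.5 without mouse 3524 (permutation p = 0.0449). Within the 5 scan batches the mean paired difference in altered share was 1.26, 11.6, -12.3, 1.72 and 0.758 points, over 6, 6, 2, 4 and 10 mice.

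**Figure D2:**
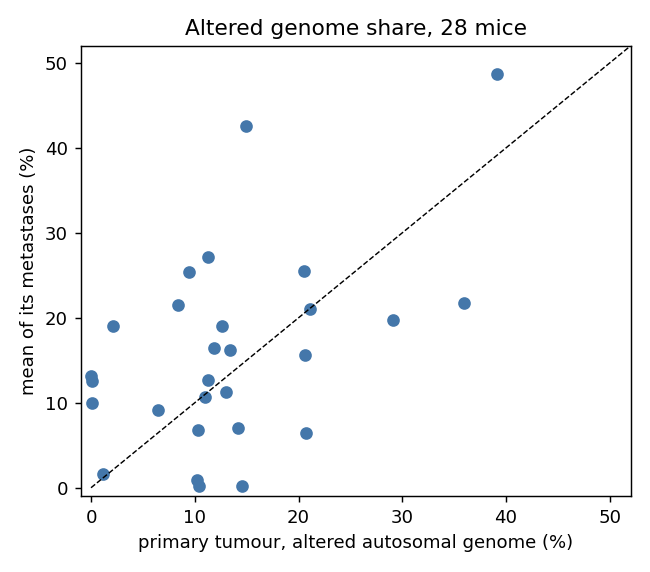
Altered share of the autosomal genome (percent) in each of 28 primary tumours (horizontal axis) against the mean of its metastases (vertical axis), with the line of equal values dashed. Metastases were higher in 16 mice and lower in 12.

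No region or chromosome differed between metastases and matched primary tumours after correction. With limma and the mouse as a block, 0 of 2383 bins of 1 Mb passed an adjusted p of 0.05, while 160 had an unadjusted p under 0.05, and 0 of 19 autosomes passed, while 3 had an unadjusted p under 0.05. Those 3 were chromosome 2, with a difference of 0.06 ± 0.03 (SE) on the log2 scale and higher in metastases of 20 of 28 mice, chromosome 9, with -0.07 ± 0.03 and higher in 7, and chromosome 15, with -0.04 ± 0.02 and higher in 11. Each had a limma adjusted p of 0.271. Of the 38 tests of chromosome-wide frequency, 0 passed the correction and 1 had an unadjusted p under 0.05. The smallest possible sign-flip p is set by the number of mice that differ, which was low throughout. It was highest for chromosome 4 loss, more frequent in metastases of 4 mice and less frequent in 5. With so few, no event could have passed the correction over 38 tests, so the count of 0 decides nothing. Gain of chromosome 2 was 20.8 percentage points more frequent in metastases, more frequent in 7 mice and less frequent in 0, with a permutation p of 0.0161 and an adjusted p of 0.613. Within the 5 scan batches that difference was 33.3, 0, 0, 50 and 26.7 points.

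On average, metastases shared more alterations with the primary tumour of their own mouse than with those of other mice. Similarity was the length called in the same direction in both samples over the length called in either. It averaged 0.35 ± 0.270 (SD, n = 28 mice) for matched pairs against 0.225 for unmatched pairs, with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. The metastases of 19 of 28 mice lay above their own mean with other primary tumours, and those of 8 were closest to their own primary tumour, while those of the other mice were closer to that of at least 1 other mouse. Part of this could be compared by slide. Matched pairs averaged 0.379 on one slide and 0.405 on different slides, and unmatched pairs 0.285 on one slide and 0.229 on different slides. In the 9 mice with a metastasis on another slide, matched pairs averaged 0.374 against 0.297 for unmatched ones, and an exact permutation test gave p = 0.0529. With mouse labels permuted only within a scan batch, an alternative chosen after seeing the data, the difference was 0.105 with a permutation p of 0.00048. The difference within each batch was 0.0847, 0.162, -0.00037, 0.058 and 0.170.

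The mice differed widely. Similarity was under 0.1 in 8 of 28 mice and at least 0.5 in 8. Similarity cannot exceed the lower altered share of a pair over the higher one, and in 6 of the 8 mice under 0.1 this limit itself lay under 0.1. In these the primary tumour or the metastases had almost no calls, with altered shares of 0.0624% in the primary tumour of mouse 3012, 0.0847% in that of mouse 3315 and 0.0305% in that of mouse 3699, and of 0.156%, 0.151% and 0.908% in the metastases of mice 3045, 3206 and 3743. The limit was 0.113 in mouse 3703 and 0.39 in mouse 3700. Mouse 3511, with a similarity of 0.683, had shares of 1.16% and 1.67% and no chromosome-wide event. In mouse 3525 the primary tumour and all 3 metastases carried loss of chromosomes 4, 13 and 14 and gain of chromosome 12, with a similarity of 0.988. In mouse 3770 all 4 samples carried loss of chromosomes 4 and 13. In mouse 3769 all 3 metastases carried gain of chromosomes 2 and 6, which were not called in the primary tumour, besides the shared loss of chromosomes 4 and 13. In mouse 3045 the primary tumour had lost chromosome 4 and the metastasis had no chromosome-wide event, while in mouse 3699 the metastasis had lost chromosomes 4 and 7 and the primary tumour had no such event. Counted per mouse, 31 chromosome-wide events were found both in the primary tumour and in a metastasis, 21 in the primary tumour alone and 40 in metastases alone. Loss of chromosome 4 made up 19, 4 and 4 of these. It was found in 23 of 28 matched primary tumours and in metastases of 23 mice. Many of the 19 would therefore coincide without any relation within a mouse. The counts over all events set all metastases of a mouse against 1 primary tumour. In the 18 mice with 1 metastasis they were 12, 18 and 22, and in the 10 mice with 2 or 3 metastases 19, 3 and 18. Events of the primary tumour alone had a median log2 ratio of 0.33 in the direction of the event there and 0.01 in the mean of the metastases. Events of metastases alone had a median of 0.47 in the metastasis with the highest value and 0.03 in the primary tumour. In 5 of these 40 the primary tumour lay at 0.1 or more in the same direction, among them the chromosome 2 gain of mouse 3769 with 0.12, against 0 of the 21 events of the primary tumour alone. Chromosome 4 loss of metastases alone had 0.18 and 0.14 in the primary tumours of mice 3315 and 3703. It had 0.06 and 0.04 in those of mice 3012 and 3699. Tumour cell content was not measured, so a sample without calls cannot be told from one with little tumour DNA. High similarity was not limited to one mouse: of 29 pairs of arrays with a similarity of at least 0.95, 20 came from different mice that carried the same set of chromosome-wide events. Pairs of different mice are far more numerous, with 1188 unmatched against 44 matched pairs of a primary tumour and a metastasis. The 20 of 29 therefore do not show that such likeness was more frequent between mice than within one.

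**Figure D3:**
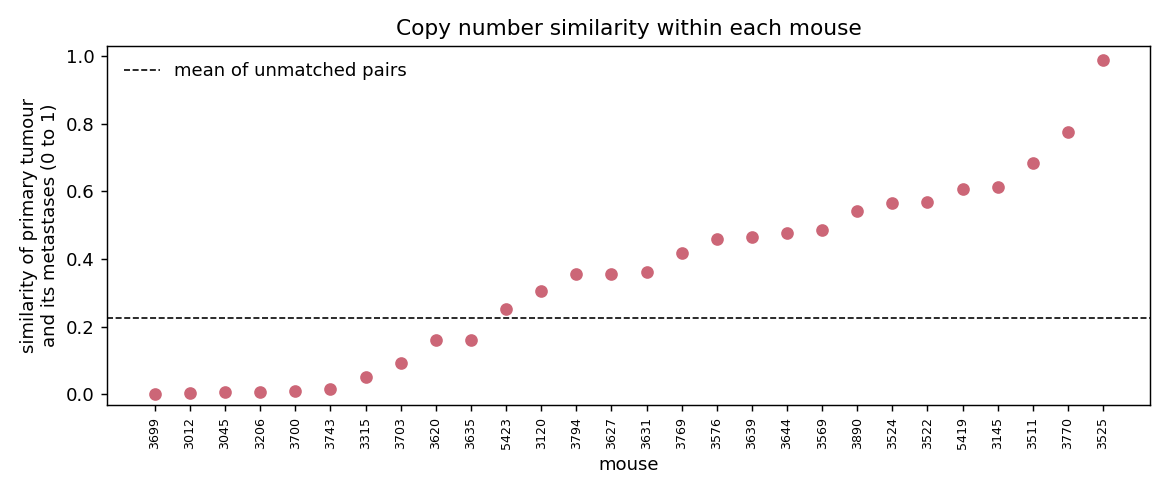
Copy number similarity (0 to 1) of the primary tumour and its metastases in each of 28 mice, ordered by value, with the mean of unmatched pairs dashed at 0.225. Similarity was under 0.1 in 8 mice and reached 0.988 in mouse 3525.

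In the 10 mice with 2 or 3 metastases, metastases of one mouse resembled each other with a mean similarity of 0.544 ± 0.301 (SD), and their primary tumour with 0.466 ± 0.284. The paired difference of 0.0784 (95% bootstrap interval -0.0908 to 0.254) was positive in 6 of 10 mice, with an exact sign-flip permutation p of 0.424. It was 0.0170 without mouse 3794 and 0.0395 without mouse 3769, 0.0174 with a calling threshold of 0.1 and 0.140 in the authors' table. The largest differences were 0.630 in mouse 3794 and 0.428 in mouse 3769, and the lowest was -0.259 in mouse 3522.

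Primary tumours of mice with and without a metastasis array were compared last. Their altered share was 13.4% ± 9.79 (SD, n = 28) and 12.5% ± 7.62 (SD, n = 26), a difference of 0.890 points (95% bootstrap interval -3.64 to 5.50) with a two-sided permutation p of 0.715. Mean shares with and without a metastasis array were 7.54% and 8.79% in scan batch 2, 12.5% and 6.80% in batch 3, and 16.2% and 15% in batch 5. Batches 1 and 4 held only mice with a metastasis array. With limma, 0 of 2383 bins passed an adjusted p of 0.05 and 63 had an unadjusted p under 0.05. With scan batch as a block, 0 passed and 211 had an unadjusted p under 0.05. Within scan batches 2, 3 and 5, with 14, 4 and 26 primary tumours, 0 passed, 591, 219 and 26 had an unadjusted p under 0.05, and the smallest limma adjusted p was 0.0594, 0.144 and 0.9999.

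Called segments under 5 Mb recurred in at least 3 mice at 232 places. Coordinates are those of the mm9 array design, and genes in these intervals are not named here. The interval shared by most mice was a loss on chromosome 4 from 112273704 to 112480643, in 34 primary tumours and 27 metastases of 40 mice. It lay inside the loss of the whole chromosome in 59 of these 61 arrays, and its mean was not lower than that of the rest of the chromosome, with mean log2 ratios of -0.53 and -0.55 and the interval lower in 24 of 61. A gain on chromosome 12 from 114670169 to 114843153 was called in 37 primary tumours and 38 metastases of 39 mice. Antigen receptor loci are rearranged and partly lost in lymphocytes of the spleen reference, so a gain called there can come from the reference. These loci were not left out. Whether this interval lies in one was not checked, so the gain cannot be assigned to the tumours. A loss on chromosome 6 from 129939104 to 129946138 was called in 36 mice. Losses followed on chromosome 11 in 30 mice, chromosomes 12 and 15 in 28 each and chromosome 19 in 22. The shared intervals of these losses and of the chromosome 6 loss held only 2 or 3 probes each. Their mean log2 ratios over all primary tumours or all metastases, called or not, lay between -0.40 and -0.94. The counts give the mice in which a segment was called there, which need not be all mice with a low signal. A gain on chromosome 2 from 85576363 to 89559349 was called in 21 mice. Inside it, a loss from 85975146 to 86032133 was called in 9 mice. Next came a loss on chromosome 4 and a gain and a loss on chromosome 7, in 19 mice each. On chromosome 9, a gain from 16625739 to 20206832 was called in 7 mice and a loss from 16533025 to 20206832 in 8. The cause was not tested. The calls are relative to the DNA of another mouse, and inherited and acquired differences were not separated. Probe noise was taken after subtracting segment means and each probe's median over all arrays. It was not independent between arrays, with a median correlation of 0.567 for arrays of one slide. The median was 0.290 for other slides of one scan batch and -0.294 for arrays of different scan batches. Subtracting a median over all arrays can itself push correlations between batches below 0, so the negative sign is not read further.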

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

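The test in this part was chosen after the values were seen. The X chromosome entered no comparison. It was called over most of its probes in 5 arrays, which is why it stands here. It was lost in metastasis 1 of mouse 3620, with a mean log2 ratio of -0.64, and in metastasis 1 of mouse 3700, with -0.76, and in 0 of 54 primary tumours. It reached the calling threshold as a gain in metastasis 2 of mouse 3145, with 0.20, and in the primary tumour and metastasis of mouse 3890, with 0.23 and 0.27. All 3 gains lay in scan batch 5, where the median X value was 0.08, and they are not weighed. The medians of batches 1 to 4 were -0.02, -0.06, -0.01 and 0.15. For the losses, an X offset shared by the slide would place other arrays of the slide nearby. The smaller of the 2 gaps to the nearest other array of the slide was -0.63, beyond the bound of 0.3, which argues against a slide offset. Both metastases also lacked the chromosome 4 loss of their primary tumour, with -0.03 against -0.44 in mouse 3620 and -0.05 against -0.53 in mouse 3700, and their similarity to it was 0.00613 and 0.0111. Metastasis 3 of mouse 3620, without X loss, lay at -0.06 on chromosome 4 with a similarity of 0.0247, and metastasis 2 at -0.47 with 0.448. Metastases 1 and 2 of mouse 3620 both carried gain of chromosome 2, which goes with 1 mouse as labelled but was found in 12 of 44 metastases. These values bear on sample identity without settling it, so a mislabelled or mixed sample stays open, and no biological explanation was tested.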

How the results depend on the processing

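The similarity of matched pairs stayed above that of unmatched pairs in all 16 alternatives run, 3 of them chosen after seeing the data, by 0.0934 to 0.145 with permutation p of at most 0.00056. The slide alternative among them kept only metastases on the slide of their own primary tumour, so it does not separate the slide. Matched pairs on different slides are not among the 16. There the difference was 0.0765 in 9 mice, with an exact permutation p of 0.0529. The counts of bins, of autosomes and of chromosome-wide frequency tests past correction were 0 in every alternative run. The frequency tests could not pass in the main setting, because few mice differed, so their count of 0 says little. The altered share in metastases against matched primary tumours kept its direction in 17 alternatives, 3 chosen after seeing the data (0.953 to 4.92 points; 1.5 to 3.06 with single mice left out) and passed the threshold in 1, with each probe's median subtracted (4.79), but not once chromosome 4 was left out there (3.66, p = 0.117). The difference between primary tumours with and without a metastasis array changed sign with a calling threshold of 0.1 (-3.31), with normexp (-0.982), with probe medians subtracted (-0.528) and without noisy arrays (-0.953), with no p under 0.05, and the cause was not tested. With each mouse left out in turn it ranged from -0.0647 to 1.83, the lowest without mouse 3890, and the difference in called segments from 7.78 to 18.5. The difference between metastasis-metastasis and primary-metastasis similarity stayed positive with p over 0.05 in all 12 alternatives (0.0174 to 0.140) and with single mice left out (0.0170 to 0.116). Without the mouse as a block, pairing ignored, the altered share difference of 2.43 had a permutation p of 0.399, the difference of 13.8 segments 0.226, and the counts stayed at 0, so the block changed no call. The chromosome 2 gain difference had an unadjusted p over 0.05 in the authors' table (16.7 points, p = 0.0622) and failed the correction throughout. Not run were the GC correction, single genes, gene bodies, antigen receptor loci and Erbb2 exon probes, and inclusion of antigen receptor loci is the main setting itself. Array noise limits short calls.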

Other observations

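Tests named here were set before their values were seen, except those without chromosome 4, within scan batches, with all metastases of a mouse, by mouse and with single mice left out, which were added after seeing the data. In 19 mice chromosome 4 was lost in the primary tumour and in at least 1 metastasis. There the lost chromosome lay lower in the metastases by a mean paired difference of -0.08 ± 0.14 (SD, 95% bootstrap interval -0.14 to -0.02), with a sign-flip permutation p of 0.0259. This used only metastases with the loss, which left out 2 metastases of mouse 3620. With all 33 metastases of these mice the difference was -0.06 ± 0.16 (SD, interval -0.13 to 0.01) with a permutation p of 0.0954, so the value depends on that choice. This test was set up to weigh tumour cell content as an explanation for autosomes that differ between the sample kinds. No autosome passed that comparison, so there was no such pattern to explain, and the value is given without adjustment and as an observation.

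The resemblance of matched samples may reflect shared descent, as a hypothesis. Without chromosome 4, lost in most samples, matched pairs averaged 0.192 against 0.0612, with a permutation p of 3.00e-05, which argues against that common loss as the whole source. The mean was carried by part of the mice. The median without chromosome 4 was 0.0622, with 16 of 28 mice under 0.1 and 3 at 0.5 or more, 15 lay above their own unmatched mean, and 6 were closest to their own primary tumour. With single mice left out the difference stayed between 0.105, without mouse 3525, and 0.138. A shared slide stays open. For pairs on different slides the exact permutation p was 0.0529 in 9 mice. The criterion written beforehand counted any p of at least 0.05 towards the slide, and it was met. That criterion was poorly chosen, since a missed threshold in 9 mice does not show that matched and unmatched pairs are alike, and the explanation is treated here as undecided for that reason, a reading adopted after the value was seen. The permutation within scan batches (difference 0.105) does not separate slides. Samples of different mice reached a similarity of 0.991, so similarity alone does not establish descent.

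Chance regroupings were counted for the 3 limma comparisons with counts of 0, so every regrouping gave at least as many calls. For bins in metastases against matched primary tumours, 100 of 100 sign assignments did, and the highest other count was 46. For autosomes 100 of 100 did, with a highest other count of 1, and for bins in primary tumours with against without a metastasis array 100 of 100 splits did, with a highest other count of 0. With real counts of 0 this outcome was fixed in advance, so the regroupings decide nothing about chance.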
